A study of Homo sapiens with 18 samples.

How the data were processed

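Total RNA from HEK293T cells was measured on 18 single-channel Affymetrix arrays, 1 per sample, with biotin-labelled RNA. The labels give 3 transfected RNAs (negative control, miR-132 mimic, miR-381 mimic; 50 nM) and 3 times of forskolin (0, 1 and 4 h; 15 µM), each in duplicate, and every array was assigned to 1 of 9 groups from its own labels. The deposited values are on a log2 scale and were made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes, with versions not given in the sources used here. RMA corrects background, normalizes quantiles across arrays and summarizes probes, so it compresses small changes of dim genes and forces the arrays to nearly 1 distribution. The values ran from 2.17 to 14.4, array medians from 6.70 to 6.79, sorted values of the arrays differed by up to 0.274, and 0 were missing. Signal over background per probe was not used here, so genes near the floor could not be told from absent ones, and for arrays only their number limits the stated precision.

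Of 33297 probe sets, the platform annotation listed 21214, of which 19460 had 1 gene symbol and 1754 several. The other 12083 were unnamed here. Symbols were updated through Entrez gene identifiers with the RefSeq gene table, and 19429 matched. Each of 18417 genes was represented by its probe set with the highest mean over all arrays, which affected the 769 genes with more than 1. Positions are not given because no genome was used here.

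Differences were estimated with limma 3.58.1 in R 4.3.3. The fit had 1 coefficient per group over all 18 arrays, 9 residual degrees of freedom and empirical Bayes moderation (prior standard deviation 0.107 with 6.57 prior degrees of freedom). The p-values were adjusted by Benjamini-Hochberg over 18417 genes with a threshold of 0.05. The comparisons were 1 and 4 h against 0 h in each transfection and in their mean, each mimic against control and against the other as a mean over the 3 times, and 4 interactions of mimic and time. The median standard error was 0.110 for 2 arrays against 2, 0.0634 for 6 against 6 and 0.155 for an interaction.

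A total of 22 gene lists was fixed from general knowledge before the data were examined, with 330 of their 356 genes measured: CREB targets, cAMP feedback, CREB pathway parts, circadian clock, immediate early, actin, SRF and YAP targets, gluconeogenesis, neuropeptides and secretory granule, ID and BMP, miR-132 reported targets, miR-381 reported targets, small RNA machinery, interferon response, G1/S and DNA replication, G2/M, p53 targets, ER stress and amino acid response, heat shock, cholesterol synthesis, TNF and NF-kB targets, other cell types, and ribosomal proteins. Some genes are in several lists. Lists were tested with limma's fry, which asks whether members move on balance 1 way and does not compare them with other genes, adjusted over the 22 lists of a comparison. The alternatives were camera with an estimated correlation and with a preset correlation of 0.01. Unlike fry, camera compares the members with all other genes, so the 2 tests also differ in the question asked. List values given with an estimated correlation are from camera. A forskolin induced set was picked in the transfection that was in neither arm, as genes with adjusted p under 0.05 and at least 1.5-fold higher at either time. It was tested with fry for 2 mimics and 2 times and adjusted over these 4 tests, not over the lists. The CREB targets by time against control were adjusted over 6 tests (2 mimics, 3 times). Sets of genes with microRNA seed sites were planned and not run, because 3' UTR sequence was not used here.

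Named genes followed a rule fixed at the same time: the 8 largest rises and 8 largest falls past the threshold whose groups do not overlap at any time, for forskolin in control cells and for each mimic; up to 4 members per list with the smallest p; NR4A1, NR4A2, NR4A3, FOS, CREM, PER1, SIK1 and PDE4D; and up to 5 rises and 5 falls for interactions and the mimics against each other. SIK1 had no probe set with its symbol alone. Genes named outside this rule are said to be so, or are members of a fixed list called when adjusted over that list.

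Alternatives fixed beforehand were the replicate number as a block, leaving out each array in turn, leaving out the dimmest 33.3% of genes, trend and robust moderation, quantile normalization applied again, arrays centred on their median, the mean over a gene's probe sets, all listed probe sets, and the arrays of a comparison alone. Alternatives added after the data were seen were the removal of the main axis of differences between replicates, the forskolin response of miR-132 minus that of miR-381, and each CREB target left out of its list.

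The fit was tested on simulated data built from the real means and spreads, with 200 genes changed among 18417 in 10 simulations. For forskolin 4 h in control cells it recovered 14.4% of changes of 1.25-fold, 81% of 1.5-fold and 100% of 2-fold. For miR-132 against control it recovered 81.2%, 99.8% and 100%, and for the interaction of miR-381 with 4 h 2%, 28.8% and 95%. False calls made up 5.02%, 4.85% and 4.4%. Real arrays share variation that these simulations lack. In 100 simulations per size, the list test of that interaction called the CREB targets lower in 1, 35 and 99 cases for shifts of 0, 0.1 and 0.2.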

Results

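HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, were reverse transfected with a negative control RNA, a miR-132 mimic or a miR-381 mimic at 50 nM. About 72 h later they received forskolin, which activates adenylyl cyclase and raises cyclic AMP, at 15 µM for 0, 1 or 4 h. The 3 transfections and 3 times gave 9 groups of 2 arrays, 18 in all. Log2 expression was read on each array, and 18417 genes were compared. Array medians lay between 6.70 and 6.79, and replicate arrays correlated at 0.995 to 0.998 across genes, which are not independent replicates. That is no sign of tight groups, since the highest correlation with an array of another group was 0.997 and 8 of 18 arrays lay closest to their own replicate. The labels number the duplicates but do not say that they were separate cultures, so every p-value measures the spread between these arrays, which may be technical. The number of arrays limits the precision. For single genes, each change given is a log2 difference with its standard error from limma. For lists and induced sets, the standard error comes from the spread of the set's mean between replicate arrays. That spread was pooled over the 9 groups and not moderated. Each adjusted p is limma's over all genes unless a list is named. Groups of 2 cannot reach an exact permutation p under 0.333, so the calls rest on the spread pooled over the 9 groups.

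The first comparison asked which genes answered to forskolin within 1 h in control cells (2 arrays against 2). The largest rise was that of the orphan nuclear receptor gene NR4A2, which went from 7.02 ± 0.05 to 11.65 ± 0.12 (SD, n = 2), a change of 4.63 ± 0.12. NR4A3 rose by 3.28 ± 0.15 and NR4A1 by 2.88 ± 0.10. The AP-1 genes FOS (3.84 ± 0.12), JUNB (2.67 ± 0.11) and FOSB (1.75 ± 0.14) rose with them, as did DUSP1, a phosphatase of MAP kinases (3.44 ± 0.15), and ATF3, a stress-induced bZIP factor (1.83 ± 0.10). TXNIP, which binds thioredoxin and limits glucose uptake, fell by 1.59 ± 0.12, and the microRNA gene MIR181B1 fell by 0.91 ± 0.15. In all, 58 genes were higher and 2 lower, of which 16 and 1 by at least 2-fold, and 820 genes had an unadjusted p under 0.05. PER1 (0.17 ± 0.10), PDE4D (0.19 ± 0.14) and CREM (0.26 ± 0.08), all with known cyclic AMP response elements, did not pass at 1 h.

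The fixed list of CREB targets, genes known to answer to the cyclic AMP response element binding protein, had 40 measured members, of which 17 rose and 0 fell (23 and 0 adjusted over the list alone). Its adjusted p was 4.7e-11 by fry, limma's directional list test, and 2.01e-07 with an estimated correlation. Of 31 immediate early genes, which are induced without new protein synthesis, 13 rose and 0 fell (16 and 0 adjusted over the list alone), with an adjusted p of 1.15e-05 (2.71e-03 with an estimated correlation). The cAMP feedback list, phosphodiesterases and other genes listed as feedback, had 2 of 21 members higher, DUSP1 and RGS2 (1.12 ± 0.10), and 3 adjusted over the list alone (adjusted p = 7.43e-04, and adjusted p = 0.0452 with an estimated correlation). DUSP1 and RGS2 are also in the list of CREB targets, and no phosphodiesterase passed over all genes at 1 h. In the ID and BMP list BAMBI (0.85 ± 0.14) and HES1 (0.80 ± 0.13) rose out of 10, against 7 higher and 1 lower adjusted over the list alone (adjusted p = 0.00898, and adjusted p = 0.0452 with an estimated correlation). The ER stress and amino acid response list held 3 risers among 14, ATF3, PPP1R15A (0.63 ± 0.12) and HERPUD1 (0.39 ± 0.08), with 4 higher and 1 lower adjusted over the list alone (adjusted p = 7.43e-04, and adjusted p = 0.0452 with an estimated correlation). INSIG1 (0.82 ± 0.09) and IDI1 (0.82 ± 0.13) rose among 12 genes of cholesterol synthesis, the same number adjusted over the list alone (adjusted p = 0.0023, and adjusted p = 0.0452 with an estimated correlation). Reported targets of miR-132 moved up through NR4A2 and HBEGF (0.56 ± 0.08), 2 of 23 (adjusted p = 2.17e-04, but adjusted p = 0.197 with an estimated correlation). Those of miR-381 held 1 riser, HES1, among 11, and 3 adjusted over the list alone (adjusted p = 0.0153, but adjusted p = 0.171 with an estimated correlation). The other 14 lists had adjusted p from 0.0509 to 0.693. Among them CCN1 (1.05 ± 0.13) and CCN2 (0.70 ± 0.13) rose in the actin, SRF and YAP list, PCK1 (0.69 ± 0.12) in gluconeogenesis and CGA (0.75 ± 0.15) among the neuropeptides. No gene of the heat shock, G2/M, ribosomal protein or other cell type lists passed limma's test. The count of 60 genes fell to 37 without the first untreated control array, 30 without the second and 36 without the second 1 h control array.

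After 4 h of forskolin, more genes had changed in control cells than after 1 h. SV2C, a synaptic vesicle protein, rose by 3.59 ± 0.14, and CGA, the alpha subunit of the glycoprotein hormones, by 3.25 ± 0.15, from 5.33 ± 0.01 to 8.57 ± 0.48 (SD, n = 2). PCK1, the gluconeogenic phosphoenolpyruvate carboxykinase, rose by 1.5 ± 0.12, CASP9 by 2.66 ± 0.09 and SLC6A17 by 1.94 ± 0.16. NR4A2 (3.19 ± 0.12), NR4A1 (2.62 ± 0.10), NR4A3 (2.43 ± 0.15), FOS (1.94 ± 0.12) and DUSP1 (1.90 ± 0.15) were still above their untreated level. TXNIP fell by 1.49 ± 0.12, the guidance molecule SEMA3A by 1.35 ± 0.14, the mTORC1 inhibitor DDIT4 by 1.10 ± 0.24 and NRG4 by 1.06 ± 0.14. There were 248 genes higher and 226 lower, 49 and 4 of them by at least 2-fold, and 2313 genes had an unadjusted p under 0.05. Of the genes that rose at 1 h, 43 were also higher at 4 h, where independent lists would share 0.781, and both TXNIP and MIR181B1 were lower at both times. The 2 comparisons share their untreated arrays. Their changes correlated at 0.428 across genes (simulated 0.5 for unchanged groups), with a covariance of 0.0111 (simulated 0.0071), so part of the overlap may come from those arrays.

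At 4 h 20 of the 40 CREB targets rose and 0 fell (26 higher and 1 lower adjusted over the list alone), with an adjusted p of 1.83e-10 (1.16e-06 with an estimated correlation). The cAMP feedback list had 6 of 21 members higher, among them PDE10A (1.34 ± 0.11), PDE7A (1.34 ± 0.16), PDE4D (0.71 ± 0.14) and CREM (0.41 ± 0.08), with 9 higher and 1 lower adjusted over the list alone (adjusted p = 3.62e-04, and adjusted p = 0.0302 with an estimated correlation). Of the immediate early genes 12 rose and 0 fell (16 and 0 adjusted over the list alone), FOSL2 by 1.34 ± 0.12 and JUNB by 1.19 ± 0.11 (adjusted p = 3.6e-04, and adjusted p = 0.0279 with an estimated correlation). Among 16 neuropeptide and secretory granule genes CGA, CHGB (0.96 ± 0.10) and TAC1 (0.98 ± 0.14) rose, the same 3 adjusted over the list alone (adjusted p = 0.00127, but adjusted p = 0.0951 with an estimated correlation). The circadian clock list shifted up (adjusted p = 0.0362) with 0 of 17 members passing over all genes in limma, and 5 higher and 1 lower adjusted over the list alone. That shift had an adjusted p = 0.132 with an estimated correlation. The p53 target list shifted down, with TP53INP1 (-0.48 ± 0.10) the 1 member of 11 that fell (adjusted p = 0.0362, but adjusted p = 0.278 with an estimated correlation). Reported miR-132 targets were up through NR4A2, HBEGF (0.35 ± 0.08) and SIRT1 (0.40 ± 0.10), 3 of 23 (adjusted p = 0.031, but adjusted p = 0.562 with an estimated correlation). The other 15 lists had adjusted p from 0.06 to 0.853. In these SIK2 (0.80 ± 0.08), a kinase that restrains CREB coactivators, rose, as did IDI1 (1.06 ± 0.13) and CCNE2 (0.62 ± 0.13), while SMAD9 (-0.48 ± 0.08) and NR5A2 (-0.79 ± 0.13) fell. The count of 474 genes went to 168 and 176 without the first or second untreated control array, to 237 without the first 4 h control array, and to 713 without the second. Fitted on the 4 arrays compared alone, 94 genes were higher and 35 lower.

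The same response was measured in cells that carried a mimic. With miR-132, 46 genes were higher and 4 lower at 1 h, and 195 and 109 at 4 h. The 4 were TXNIP (-1.16), TGIF1 (-0.69), ZNF250 (-0.44) and WDCP (-0.43), the last 3 named after their values were seen. With miR-381 there were 26 higher and 1 lower at 1 h, and 101 and 49 at 4 h. In all 3 transfections 23 genes were called higher at 1 h, among them NR4A1, NR4A2, NR4A3, FOS, JUNB, DUSP1 and RGS2, and TXNIP was the 1 gene called lower in all 3. At 4 h 90 genes were higher and 29 lower in all 3, with CGA, PCK1, CHGB and PDE4D among the first. Of 40 CREB targets, 13 rose at 1 h and 18 at 4 h with miR-132, against 10 and 15 with miR-381, and 0 fell in any of these comparisons by limma's adjusted p. Adjusted over the list alone these were 19 at 1 h and 22 higher and 1 lower at 4 h with miR-132, and 20 and 21 with miR-381. Averaged over the 3 transfections (6 arrays against 6), 145 genes were higher and 69 lower at 1 h, and 815 and 934 at 4 h. With miR-132 the 50 genes of 1 h became 25, 28, 32 and 19 without the first or second untreated array or the first or second 1 h array. The 304 genes of 4 h became 200, 201 and 139 without the first or second untreated or the first 4 h array, and 111 higher and 21 lower without the second 4 h array. With miR-381 the 150 genes of 4 h became 95, 92, 81 and 88 without the first or second untreated or 4 h array. The mean over transfections gave 126 genes at 1 h and 1161 at 4 h without the first untreated control array, 142 at 1 h without the second 1 h miR-381 array, and 1140 at 4 h without the second 4 h miR-132 array. With the arrays of each comparison alone, the 4 h counts were 75 higher and 9 lower with miR-132, and 67 and 14 with miR-381.

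The next comparison asked what the miR-132 mimic changed, as the mean over the 3 times (6 arrays against 6). STMN1, which encodes the microtubule-destabilising protein stathmin, fell by 1.88 ± 0.05. A second probe set of this gene changed by -0.04, so the fall was seen with 1 of its 2 probe sets. DAZAP2 fell by 1.28 ± 0.06, CDK19, a kinase of the Mediator complex, by 1.14 ± 0.07, C1D by 1.08 ± 0.07 and the actin-bundling gene FSCN1 by 0.98 ± 0.11. Higher genes were led by UPK1B (1.24 ± 0.09), HMOX1, the inducible heme oxygenase (1.21 ± 0.11), SCOC-AS1 (1.19 ± 0.08), ENPP2, which makes lysophosphatidic acid (1.16 ± 0.07), and the metallothionein MT1F (1.15 ± 0.06). There were 1502 genes higher and 1645 lower, but 11 and 4 by at least 2-fold. The probe set of the gene MIR132, chosen after its values were seen, changed by 0.08 ± 0.14. The mimic is a short RNA added from outside, so that gene is no check of the transfection.

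Among 23 reported targets of miR-132, 12 fell and 2 rose (16 and 2 adjusted over the list alone). GMFB (-0.78 ± 0.07), PAIP2 (-0.55 ± 0.07), ZEB2 (-0.46 ± 0.06) and HBEGF (-0.45 ± 0.05) fell furthest, RB1 (-0.42 ± 0.07), SIRT1 (-0.37 ± 0.05) and PTBP2 (-0.36 ± 0.06) fell too, and NR4A2 (0.27 ± 0.07) and ITPKB (0.23 ± 0.07) rose. The NR4A2 mean came from the forskolin times: it was 6.83 ± 0.17 with miR-132 against 7.02 ± 0.05 in control (SD, n = 2) without forskolin, and 11.01 ± 0.08 against 10.22 ± 0.12 at 4 h. The list's adjusted p was 1.4e-05, but adjusted p = 0.0641 with an estimated correlation. The CREB pathway parts had 7 of 22 members lower and 0 higher, the same adjusted over the list alone, including the adenylyl cyclase ADCY3 (-0.48 ± 0.07), the coactivator CRTC3 (-0.24 ± 0.05), CREB1 itself (-0.22 ± 0.04) and the protein kinase A subunit PRKACA (-0.21 ± 0.05). That list had an adjusted p = 0.00188, but adjusted p = 0.326 with an estimated correlation. CREB targets had 7 higher, such as FOSB (0.52 ± 0.08) and PCK1 (0.43 ± 0.07), and 4 lower, such as PDE10A (-0.58 ± 0.07) and JUNB (-0.31 ± 0.07), or 12 and 4 adjusted over the list alone. Their shift was upward (adjusted p = 3.34e-04, but adjusted p = 0.158 with an estimated correlation, and 0.0529 with each array centred on its median). By time, and adjusted over the 6 tests of this list by mimic and time in place of the 22 lists, the list differed from control by 0.081 at 0 h (adjusted p = 0.00107), -0.015 at 1 h (adjusted p = 0.682) and 0.160 at 4 h (adjusted p = 1.49e-04). Antiviral genes of the interferon list rose in 4 of 18 cases, IFIH1 (0.51 ± 0.06), IFIT1 (0.47 ± 0.08), OAS3 (0.45 ± 0.08) and IFI6 (0.29 ± 0.05), and 5 adjusted over the list alone (adjusted p = 0.00244, but adjusted p = 0.368 with an estimated correlation).

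**Figure D1:**
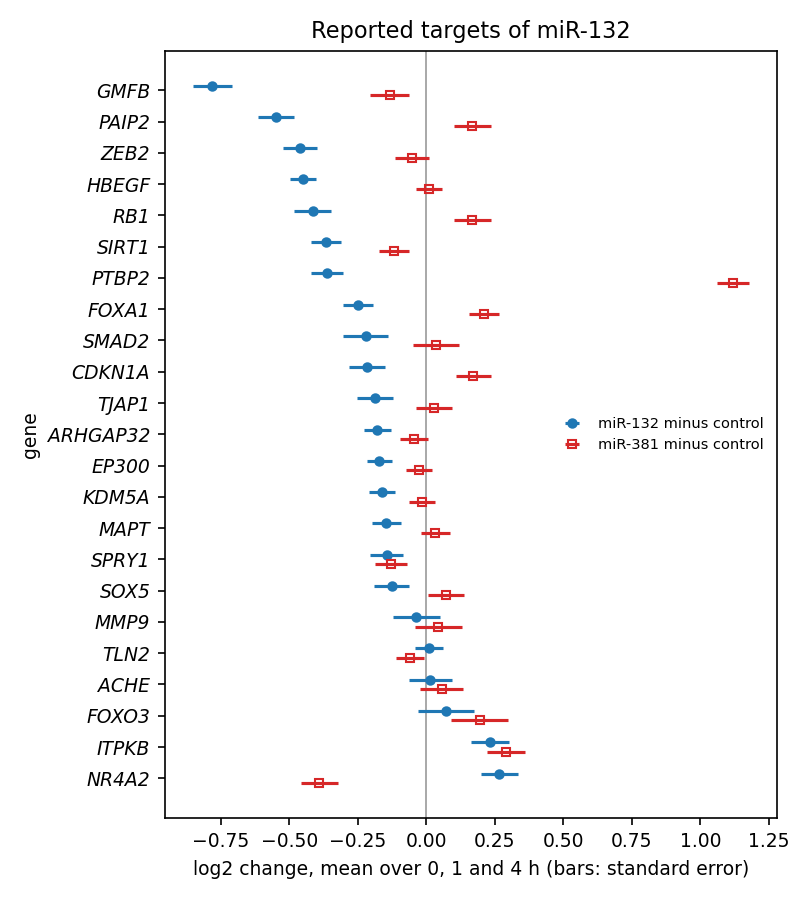
Log2 change with each mimic against control RNA for the 23 measured reported targets of miR-132, as the mean over 0, 1 and 4 h (x axis; 6 arrays against 6), one gene per line, with bars for the standard error. Filled circles are miR-132 and open squares miR-381: GMFB lies at -0.78 with miR-132, and PTBP2 lies at -0.36 with miR-132 and at 1.12 with miR-381.

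Of 13 ribosomal protein genes 5 fell, among them RPL10 (-0.31 ± 0.05) and RPL32 (-0.24 ± 0.06), and 1 rose, or 7 and 1 adjusted over the list alone (adjusted p = 3.34e-04, but adjusted p = 0.326 with an estimated correlation). Reported targets of miR-381 fell in 3 of 11 cases with miR-132, YAP1 most (-0.56 ± 0.06), and in 5 adjusted over the list alone (adjusted p = 3.34e-04, but adjusted p = 0.203 with an estimated correlation). Cholesterol synthesis had 4 of 12 genes lower, such as LSS (-0.40 ± 0.07) and SREBF2 (-0.27 ± 0.05), the same 4 adjusted over the list alone (adjusted p = 0.0096, but adjusted p = 0.368 with an estimated correlation). The Argonaute gene AGO1 (-0.50 ± 0.05) was 1 of 3 members of the small RNA machinery that fell, out of 13, with 1 higher and 3 lower adjusted over the list alone (adjusted p = 0.0448, but adjusted p = 0.587 with an estimated correlation). In the neuropeptide list CHGB (0.50 ± 0.06) and TAC1 (0.50 ± 0.08) rose, and 3 genes adjusted over the list alone (adjusted p = 0.0106, but adjusted p = 0.368 with an estimated correlation). PCK1 and PPARGC1A (0.27 ± 0.06) rose in the gluconeogenesis list of 12, with 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.0336, but adjusted p = 0.539 with an estimated correlation). The PCK1 mean, also given among the CREB targets above, came from 4 h. There its arrays lay at 8.82 and 8.83 with miR-132 against 7.59 and 7.61 in control. Untreated arrays lay at 6.26 and 6.13 against 6.12 and 6.07. CHGB arrays overlapped between miR-132 and control without forskolin, and were higher with miR-132 at 1 and 4 h. The ER stress list had 4 members higher, such as DDIT3 (0.26 ± 0.07), and SESN2 (-0.32 ± 0.06) lower, or 5 and 1 adjusted over the list alone (adjusted p = 0.0194, but adjusted p = 0.41 with an estimated correlation). The other 11 lists had adjusted p from 0.0615 to 0.721. They held single movers such as FAS (0.63 ± 0.08) among p53 targets, KLF10 (-0.60 ± 0.05) among immediate early genes, SMAD6 (-0.53 ± 0.06) and LUM (0.55 ± 0.09), a marker of fibroblasts in the list of other cell types, where 1 of 17 markers passed.

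The miR-381 mimic was compared with control in the same way (6 arrays against 6). TGFBR3, a coreceptor for TGF-beta, fell by 1.10 ± 0.05, the hyaluronidase CEMIP2 by 1.10 ± 0.07, the lipid transfer gene PLTP by 1.07 ± 0.05, and GOLM2 by 0.90 ± 0.06. MAGEB2 (1.5 ± 0.14), SAMD9 (1.40 ± 0.07), the sodium channel gene SCN2A (1.36 ± 0.11), the cytidine deaminase APOBEC3B (1.25 ± 0.07) and HMOX1 (1.23 ± 0.11) rose. PTBP2, a splicing regulator that fell with miR-132, rose by 1.12 ± 0.06. The counts were 1428 genes higher and 1537 lower, 11 and 3 of them by at least 2-fold. Quantile normalization applied again gave 1895 higher and 1323 lower, so the balance of directions depended on the scaling.

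Reported targets of miR-381 did not move together: of 11, WEE1, a G2/M checkpoint kinase, fell (-0.42 ± 0.06) and NR5A2 rose (0.29 ± 0.08), the same adjusted over the list alone, with an adjusted p of 0.371 for the list. The 3 probe sets of WEE1 ran from -0.42 to 0.09. Ribosomal protein genes fell in 6 of 13 cases and rose in 0 (7 and 0 adjusted over the list alone), such as RPL32 (-0.37 ± 0.06) and RPL10 (-0.26 ± 0.05) (adjusted p = 7.78e-05, but adjusted p = 0.413 with an estimated correlation). CREB targets had 2 higher, ATF3 (0.25 ± 0.06) and PDE7B (0.24 ± 0.06), and 7 lower, among them FOS (-0.58 ± 0.07), CGA (-0.54 ± 0.09), NR4A2 (-0.39 ± 0.07) and PCK1 (-0.26 ± 0.07), or 6 and 9 adjusted over the list alone. Their downward shift had an adjusted p = 0.015, but adjusted p = 0.653 with an estimated correlation and 0.161 with arrays centred on their medians. This mean hides opposite signs, again with p adjusted over 6 tests: the list was higher than in control by 0.082 without forskolin (adjusted p = 0.00141), and differed by -0.110 at 1 h (adjusted p = 7.94e-04) and -0.143 at 4 h (adjusted p = 2.31e-04). Without forskolin the CGA, NR4A2 and PCK1 arrays overlapped between miR-381 and control, so their lower means came from the forskolin times. FOS was lower already without forskolin, at 6.14 and 6.18 with miR-381 against 6.51 and 6.71 in control. The adjusted p of the mean shift was 0.0506 without the second untreated control array, and 0.0644 without the second 1 h control array. OAS3 (0.67 ± 0.08) was the 1 gene of the interferon list that rose, also adjusted over the list alone (adjusted p = 0.0179, but adjusted p = 0.956 with an estimated correlation). Reported targets of miR-132 had 3 higher, PTBP2, ITPKB (0.29 ± 0.07) and FOXA1 (0.21 ± 0.05), and 1 lower, NR4A2, the same adjusted over the list alone (adjusted p = 0.0267, but adjusted p = 0.956 with an estimated correlation). The other 17 lists, apart from the miR-381 targets above, had adjusted p from 0.193 to 0.912. Their largest single movers included ZMAT3 (-0.83 ± 0.06), a p53 target, CCND1, which encodes cyclin D1 (-0.65 ± 0.06), NPY (0.50 ± 0.07), INSIG1 (-0.46 ± 0.05) and TNRC6B (-0.42 ± 0.05). In the list of other cell types and among TNF and NF-kB targets no member passed limma's test.

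Set directly against each other, without the control arrays, the mimics differed in 4467 genes, 2246 higher and 2221 lower with miR-132. STMN1 (-1.93 ± 0.05), PTBP2 (-1.48 ± 0.06), ZC3H6 (-1.42 ± 0.07), EDIL3 (-1.38 ± 0.10) and C1D (-1.36 ± 0.07) were lower with miR-132 than with miR-381. SCOC-AS1 (1.51 ± 0.08), OSTN (1.42 ± 0.10), ARRDC4 (1.25 ± 0.10), CTH (1.17 ± 0.07) and PLTP (1.14 ± 0.05) were higher. NR4A2 was 0.66 ± 0.07 and FOS 0.72 ± 0.07 higher with miR-132. Of the CREB targets 13 were higher and 2 lower (13 and 3 adjusted over the list alone), with an adjusted p = 1.18e-05, but adjusted p = 0.0694 with an estimated correlation. Of the reported miR-132 targets 15 were lower and 1 higher (16 and 1 adjusted over the list alone), with an adjusted p = 1.44e-06, but adjusted p = 0.0694 with an estimated correlation. In all, 10 lists passed, and 0 with an estimated correlation in limma's camera.

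The question in the series title, whether the mimics change the forskolin response of CREB targets, was tested as an interaction, the rise with a mimic minus the rise in control. The 40 CREB targets rose by 0.93 on average at 1 h in control cells and by 0.74 with miR-381, a difference of -0.192 ± 0.038. At 4 h they rose by 0.77 and 0.54, a difference of -0.225 ± 0.038. In these comparisons 30 and 33 of the 40 genes had the smaller rise with miR-381. The adjusted p was 0.00123 at 1 h (0.00145 with an estimated correlation) and 4.46e-04 at 4 h (1.54e-04 with an estimated correlation). Centring the arrays on their medians took the 1 h value to 0.184. The difference stayed at -0.188, while the SD of the list mean between replicates went from 0.027 to 0.047. No single gene passed over all genes in limma for miR-381, with 302 genes at an unadjusted p under 0.05 at 1 h and 383 at 4 h. The smallest adjusted p, 0.324, belonged to 4 h. Adjusted over the list alone, 2 CREB targets passed at 1 h, NR4A2 (-0.69 ± 0.17) and JUNB (-0.67 ± 0.16), and 5 at 4 h, CGA, GEM, NR4A2, EGR1 and PDE10A, all with the smaller rise. CGA rose by 1.94 with miR-381 against 3.25 in control, and GEM by 0.74 against 1.82, while NR4A2 differed by -0.67 ± 0.17. Leaving out 1 control array at 4 h gave larger differences, -1.64 for CGA without the first and -1.32 for GEM without the second. Leaving out the other control array would make each difference smaller. The CGA control arrays at 4 h lay apart, at 8.23 and 8.91.

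**Figure D2:**
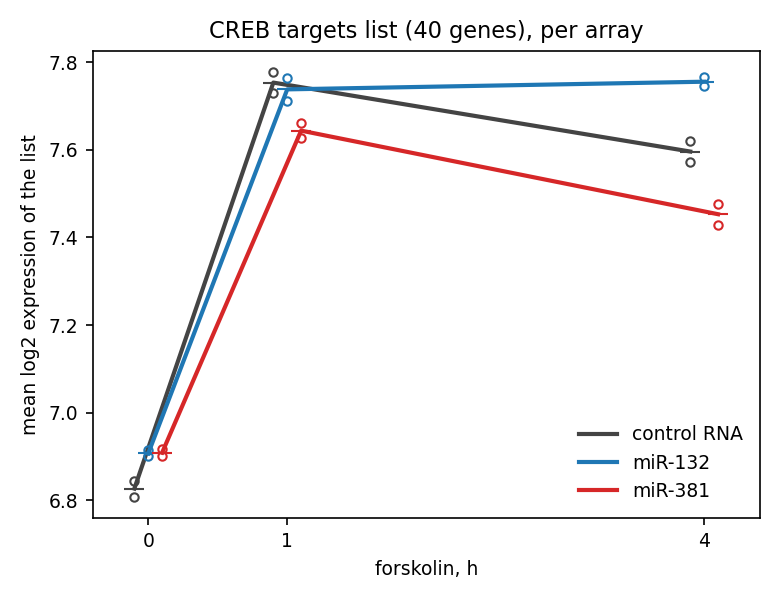
Mean log2 expression of the 40 measured CREB targets on each array (open circles) against hours of forskolin, with lines through the means of the 2 arrays per group (dashes). The miR-381 arrays rise by 0.74 at 1 h and 0.54 at 4 h, against 0.93 and 0.77 in control, and the series are shifted sideways by a small step so that circles can be told apart.

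With miR-132 the CREB targets rose by 0.83 at 1 h and 0.85 at 4 h, and 25 and 22 of the 40 genes had the smaller rise, so at 4 h the larger mean (median difference -0.022) was not shared by most genes. The interaction did not pass at either time when adjusted over the 22 lists (adjusted p = 0.0852 and 0.511). At 1 h it passed, as a smaller rise, when adjusted over the 4 tests of this list by mimic and time (adjusted p = 0.00517), and over the 22 lists with the main axis of replicate differences removed (adjusted p = 0.0317). That call thus turns on the number of tests adjusted for and on the processing. It also reflects the starting level: the list lay 0.081 higher with miR-132 than in control without forskolin, and differed by -0.015 at 1 h. The smaller rise thus came mostly from the untreated arrays, and a lower level under forskolin was not seen at 1 h. Untreated miR-381 arrays lay 0.082 above the same control arrays. With 0 genes called over all genes at 1 h by limma (261 at an unadjusted p under 0.05), 3 genes passed at 4 h, where 313 had an unadjusted p under 0.05. NTS, which encodes neurotensin, rose by 2.34 with miR-132 against 1.18 in control, a difference of 1.16 ± 0.15 (adjusted p = 0.0135). CHGB, chromogranin B, rose by 1.99 against 0.96, a difference of 1.03 ± 0.14 (adjusted p = 0.0135). PCK1 rose by 2.63 against 1.5, a difference of 1.13 ± 0.17 (adjusted p = 0.0436). NR4A2 differed by 0.99 ± 0.17 and did not pass (adjusted p = 0.096). Adjusted over the list alone, PCK1, NR4A2, FOS and FOSB among the CREB targets had the larger rise at 4 h with miR-132, and EGR1 the smaller. The count of 3 was 0 without the first untreated miR-132 array, the second untreated control array or the second 4 h control array. It was 1 without the second untreated miR-132 array or the first 4 h control array (NTS), the second 4 h miR-132 array (CHGB) or the first (ACTBL2, at 1.43, in place of the 3). It was also 0 in the arrays of this comparison alone, and 0 without the dimmest genes, a step that removed NTS and CHGB themselves and left PCK1 at an adjusted p of 0.0581.

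**Figure D3:**
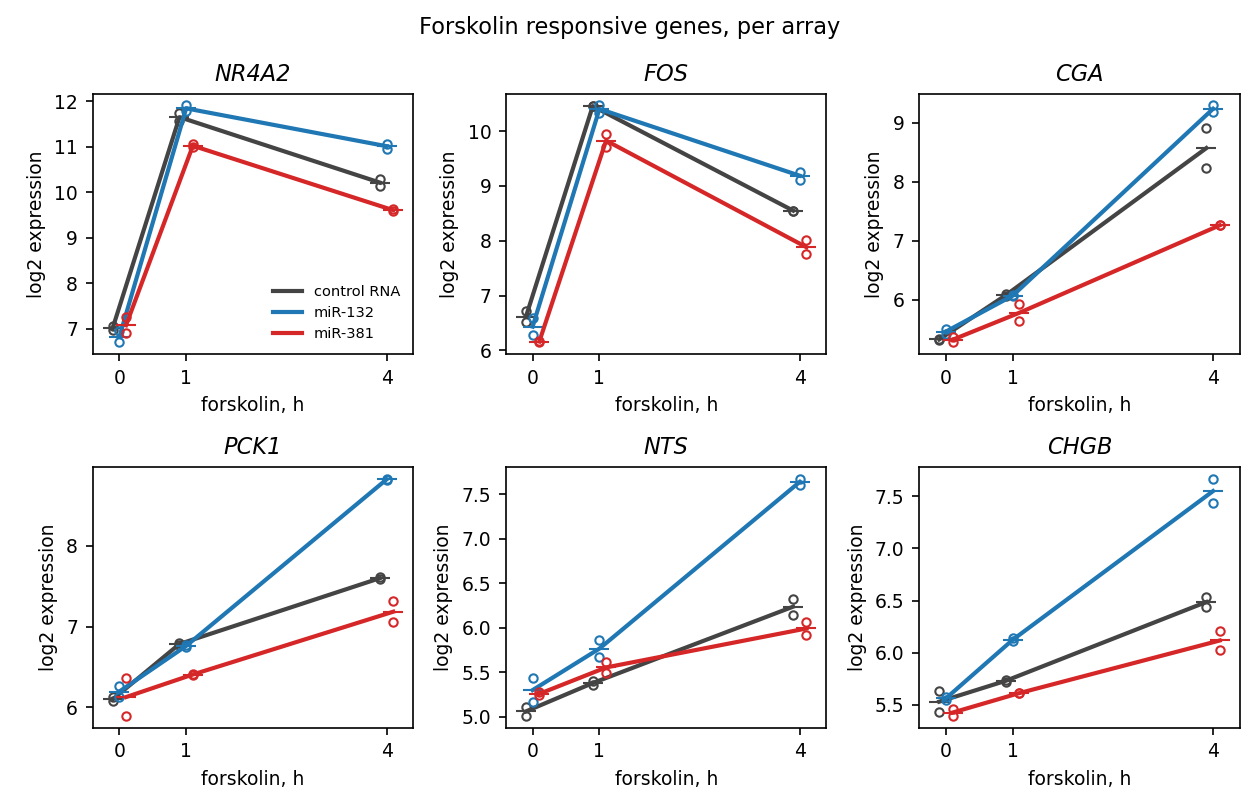
Log2 expression of 6 genes on each array (open circles) against hours of forskolin, with lines through the means of the 2 arrays per group (dashes), shifted sideways by a small step. At 4 h CGA is at 7.26 with miR-381 and 8.57 in control, and NTS is at 7.64 with miR-132 and 6.23 in control; each panel has its own y axis, which does not start at 0.

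The same question was put to genes picked by their rise in the transfection that was in neither arm, so that picking favoured neither. The 125 genes induced in miR-132 cells rose by 0.71 at 4 h with miR-381 and by 0.93 in control, a difference of -0.220 ± 0.058, and 108 of them rose less (adjusted p = 0.0156, over the 4 tests of induced sets, as are the others given for them). At 1 h the difference was -0.149 ± 0.058 (adjusted p = 0.0555). The 84 genes induced in miR-381 cells differed by -0.094 ± 0.054 at 1 h and 0.084 ± 0.054 at 4 h between miR-132 and control, and neither passed (adjusted p = 0.137 and 0.221). Without the second untreated control array the 4 h value with miR-381 had an adjusted p of 0.0534, without the first untreated miR-381 array 0.0806, and without the first 4 h miR-381 array 0.0564. The 1 h value passed without the second untreated miR-381 array (0.0416) and without the first 1 h miR-381 array (0.0489). With centred arrays the 4 h value had an adjusted p of 0.0549. The CREB targets made up 17 of the 125 genes.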

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

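The difference between the mimics, the removal of the main axis of replicate differences, the leaving out of list members and the test of the size of the NTS, CHGB and PCK1 difference were chosen after the results were seen.

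The rise of the CREB targets list under forskolin differed between miR-381 and control cells by -0.192 at 1 h and -0.225 at 4 h on the log2 scale, by the interaction in fry. No single array carried the 4 h difference (highest adjusted p 0.00273 with any 1 array left out), and it was -0.225 after the replicate axis was removed. The list started 0.0822 higher in untreated miR-381 cells (SE 0.027), which is under 0.5 times the 4 h difference. At 1 h it is a larger part, and a higher start may account for some of the smaller rise at both times. Under forskolin the list differed from control by -0.110 at 1 h and -0.143 at 4 h. It is unsettled whether all forskolin responses were weaker: 40 genes lowered by forskolin in miR-132 cells fell less with miR-381 than in control by 0.107 ± 0.101 (adjusted p = 0.641 by fry, over 4 tests), and the induced set at large also rose less, by -0.220 at 4 h, which overlaps the list in 17 genes.

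At 4 h NTS (1.16), CHGB (1.03) and PCK1 (1.13) rose more with miR-132 than with control, by the interaction in limma, where 313 genes had an unadjusted p under 0.05. The calls depend on single arrays: without 4 of the 8 arrays 0 of the 3 genes passed limma's adjusted threshold, and without 1 array alone did 2 pass, so the calls may rest on the arrays at hand. The size of the differences held without 1 array, with 0.916 as the lowest difference of any of the 3 genes. Genes that pass limma's test tend to have close duplicates, so this outcome was likely beforehand and is no separate support. The size also stayed after the replicate axis was removed (median of the 3 genes 1.14). The set induced in miR-381 cells rose by 1.24 with miR-132 and by 1.15 in control, a difference of 0.0838 ± 0.054, so a gain shared by all induced genes was not seen at the size these genes would need, although they were picked for large differences.

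Directly between the mimics, at 4 h 9 genes rose more with miR-132 than with miR-381 and 0 rose less by limma's adjusted p (383 at an unadjusted p under 0.05): CGA (1.84), NR4A2 (1.66), NTS (1.60), TAC1 (1.60), PCK1 (1.57), CHMP1B (1.44), CHGB (1.30), FOS (1.03) and SEMA6A (0.90). At 1 h 0 genes passed in limma, with 336 at an unadjusted p under 0.05. Of the lists, 5 rose more at 4 h with miR-132. CREB targets differed by 0.304 (adjusted p = 5.72e-05, and adjusted p = 1.16e-04 with an estimated correlation). ER stress and amino acid response differed by 0.218 and cholesterol synthesis by 0.193 (both adjusted p = 0.0392, and adjusted p = 0.0373 with an estimated correlation). Neuropeptides and secretory granule differed by 0.311 and the reported miR-132 targets, which include NR4A2, by 0.154 (both adjusted p = 0.0392, but adjusted p = 0.0505 with an estimated correlation).

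For the comparisons of 6 arrays against 6, 100 of the 108 arrangements that keep the other factor balanced were drawn, the real one included. For forskolin 4 h (1749 genes, highest other 329), miR-132 (3147 genes, highest other 434), miR-381 (2965 genes, highest other 655) and the mimics against each other (4467 genes, highest other 621), 1 arrangement gave as many genes, the real one. For forskolin 1 h (214 genes) 2 arrangements did, the real one and 1 other. Both shares lie under the 5% set beforehand, which speaks against an arbitrary labelling of single arrays. Chance differences between cultures are not excluded, because duplicates may come from 1 culture and the test regroups single arrays. In the forskolin 1 h comparison the other arrangement called 883 genes. It puts all 6 arrays at the low end of the replicate axis on 1 side, which points to a structure of the samples. With the axis removed, that arrangement called 0 genes by limma's adjusted p (4 at an unadjusted p under 0.05) and the real one 478. Both counts are partly built in, since the removal takes out what the other arrangement follows and shrinks the spread of the real one. In the remaining comparisons the highest other arrangement kept 5 of the 6 arrays of the real side together. Its counts thus hold much of the real difference and are not those of an arbitrary labelling. The median count of the other arrangements was 0 genes in every comparison. With the axis removed, the highest other arrangement in these remaining comparisons called more genes. It called 1097 for forskolin 4 h, 995 for miR-132, 2081 for miR-381 and 1969 for the mimics against each other. The real ones called 3031, 4817, 4408 and 6100.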

How the results depend on the processing

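The removal of the replicate axis and the leaving out of list members were chosen after the data were seen. Values with list members left out are not given here, so whether the CREB list calls depend on a single member is not shown. The number of arrays limits all results, and signal over background was not used. Of 234 calls, each of a named gene in 1 comparison, 176 were kept in every alternative, 58 were lost in at least 1 (56 of them with an array left out) and 0 reversed. The seed site sets were not run. Where the cause of a change is not given, the cause was not tested.

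Fitted on the arrays of a comparison alone, which have fewer degrees of freedom, forskolin called 26 genes at 1 h and 129 at 4 h in control, 11 and 84 with miR-132, and 14 and 81 with miR-381, and the interaction of miR-132 with 4 h called 0 (3 in the fit of all arrays). With the replicate axis removed, which shrinks the spread by construction, the counts were 128 and 1220, 106 and 786, 46 and 399, for the means 478 and 3031, for miR-132 against control 4817, and for the interaction 6. That interaction called 5 with trend and robust moderation and 0 without the dimmest genes, 313 having an unadjusted p under 0.05 in limma's fit.

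Replicate numbers were not taken to pair the arrays, because deviations of same-numbered arrays correlated from -0.33 to 0.55 over 36 pairs of groups (median 0.111, 19 over 0.1 and 10 under -0.1). The 3 pairs within miR-132 all lay over 0.1 (0.553, 0.160 and 0.146). By deviations from the group mean, 16 of 18 arrays correlated best with an array of their own number. The 2 deviations of a group mirror each other, so these are not separate cases. Together these values are a hint from the data that some arrays share more than a number. With the replicate block no count moved by over 1.5 times, PCK1 lost its interaction call (adjusted p 0.0837), and the CREB list by miR-132 at 1 h had an adjusted p of 0.00394 (0.0317 with the axis removed).

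Centring took the adjusted p of the CREB list to 0.184 for miR-381 at 1 h, 0.0529 for miR-132 against control and 0.161 for miR-381 against control, and that of the induced set for miR-381 at 4 h to 0.0549. The CREB differences remained (-0.188, 0.060 and -0.069), and the SD of the list mean between replicates rose from 0.027 to 0.047. With an estimated correlation, lists against control gave 0.158 (CREB), 0.0641 (miR-132 targets) and 0.326 (ribosomal) with miR-132, and 0.653 (CREB) and 0.413 (ribosomal) with miR-381. The preset correlation gave 0.370 for CREB with miR-381. The induced set for miR-381 at 1 h passed after quantile normalization (0.0305), axis removal (3.78e-04), with estimated (0.0340) and preset (8.2e-12) correlation, and with the CREB list in its place (1.11e-04), each adjusted over 4 tests. For miR-132 it passed with the axis removed (0.0197 at 1 h, 0.0300 at 4 h), the preset correlation (2.37e-04, 0.0216) and, at 1 h, with the CREB list in its place (0.00517). That last test is the one with an adjusted p of 0.0852 over the 22 lists.

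Without 1 array of the groups compared, where a lone array was assumed to vary like the other groups, forskolin called 30 to 45 genes at 1 h and 168 to 713 at 4 h in control, 19 to 32 and 1.3e+02 (111 higher and 21 lower) to 201 with miR-132, 19 to 23 and 81 to 95 with miR-381, and 126 to 186 and 1140 to 2260 for the means. The 4 h interactions called 0 to 2 with miR-132 and 0 to 1 with miR-381. Without a miR-381 array at 0 or 4 h, which enters the miR-132 interaction through the pooled spread alone, it called 4 or 3. The CREB list for miR-381 against control had an adjusted p of 0.00585 to 0.0644, and the induced set for miR-381 0.0416 to 0.161 at 1 h and 0.00340 to 0.0806 at 4 h.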

Other observations

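The list of NRF2 targets and the survey of small nucleolar RNA genes were chosen after the results were seen, and so were the genes named here. Both mimics raised HMOX1 (1.21 with miR-132 and 1.23 with miR-381), LGALS3BP (1.14 and 1.05), a secreted glycoprotein, RRAGC (1.03 and 0.92), a GTPase of the amino acid branch of mTORC1 signalling, and SLC7A11 (0.76 and 0.71), the cystine importer. Both lowered FZD6, a Wnt receptor (-0.66 and -0.82), and MAP3K20 (-0.57 and -0.58), which senses stalled ribosomes. Among 176 small nucleolar RNA genes, which guide modification of ribosomal RNA, 32 fell and 1 rose with miR-132, and 70 fell and 1 rose with miR-381, with SNORD49A at -0.72 and -0.70. With either mimic most did not pass, and no list test was run on this group, which was picked after some members were seen. The medians were -0.09 (quartiles -0.227 and 0.005) and -0.16 (quartiles -0.321 and -0.025), and both stayed negative after quantile normalization (-0.08 and -0.15) and after centring (-0.10 and -0.17).

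Genes called for both mimics went the same way in 758 cases (401 higher, 116 expected of independent lists; 357 lower, 137 expected) and opposite ways in 275. Both comparisons use the same control arrays, and unchanged groups simulated against them correlated at 0.5, above the 0.293 observed. The covariance, 0.00766, lay above the simulated 0.00236. With the control arrays split so that each mimic had its own, the effects correlated at 0.135 and 0.228 in the 2 splits, and at 0.120 and 0.204 with the replicate axis removed, so neither shared arrays nor that axis accounts for all of it. A deviation common to both control duplicates would stay shared after this split, so it is not excluded. The small nucleolar RNA medians kept at least 89.8% of their size when the axis was removed. The control cells also received a transfected RNA, so a response of equal size to any transfected RNA would cancel in these differences. As a hypothesis, a feature of the control RNA or its cultures, or a response to both mimics that the control RNA lacks, may lie behind the shared part. The design has 1 control RNA, and this was not tested.

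Since HMOX1 and SLC7A11 are targets of the oxidative stress factor NRF2, a hypothesis was that both mimics raise the NRF2 program. A list of 15 other measured NRF2 targets rose with miR-132 (a fry p-value of 0.00324, but 0.221 with an estimated correlation), where NQO1, TXNRD1, SRXN1, ME1 and ABCC2 rose and PGD fell. With miR-381 0 rose and FTL fell (a p-value of 0.279 in fry, limma's rotation test). A rise of this list with both mimics was therefore not seen. Its mean change with miR-381 was -0.034, and a small rise is not excluded.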
